A study of Mus musculus with 11 samples.

How the data were processed

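Exome libraries of the mT3-2D cell line (1), WT tumours (5) and SCID tumours (5) were made from 1 µg of genomic DNA of cells or whole tumour tissue with an Agilent SureSelect mouse exome kit and sequenced as paired reads of 150 bp on an Illumina HiSeq to a mean depth of 200-fold, per the labels' protocols. Variants were called with GATK on the mouse build mm10, per the submitters' processing notes. The aligner, the filters against germline variants and coverage, and the use of a matched normal are not given in the sources used here. Tumour tissue also holds host cells, so a call can come from tumour or host DNA.

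The score of each peptide is its predicted affinity in nM from NetMHC 4.0, per the file headers, given for the mutant and the reference peptide. The ratio of reference to mutant score was computed by the authors and deposited beside them. The number of occurrences per library is the authors' own and counts how often a peptide appeared in their prediction output, not reads; it carries no depth. These integers were used as called or not called, except for 3 peptides whose number varied between the libraries that carried them, where the numbers themselves were compared. The depth behind each call is unknown. Library columns are headed by an index sequence under the name of the group, per the file headers, so each library's group was known and its replicate number was not. Libraries were given letters (WT-a to WT-e, SCID-a to SCID-e) as names only. The labels describe each tumour as a separate sample of its group.

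From these tables, peptide lines were merged to candidates, each 1 substitution: lines with an identical mutant peptide were joined, as were lines of 1 gene with the same amino-acid change whose peptides overlapped by at least 3 residues without mismatch, or by at least 8 with at most 1. The rule was set after the files were seen, because they give no base positions. Each candidate took its strongest predicted peptide. Sets were recomputed from the library columns and held the same lines as the authors' set tables. Of the 128 gene names, 121 matched the reference gene table (GRCm38.p6, the assembly of mm10) by symbol or a unique synonym, which gave 135 of the 142 candidates a gene location; coordinates are those of the gene, not of the substitution. Base changes were inferred from amino-acid changes through the genetic code, taking every codon pair that differs by 1 base.

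Named candidates follow a rule fixed before the data were examined: the authors' top candidates and picks, the 5 genes with the strongest mutant peptide in each set, up to 5 members of each fixed gene list, and single genes fixed in advance, among them Trp53 and Prkdc. Shroom4, AC133103.6, Ocrl, Spry3 and Sox3 are named beyond it, after their values were seen, where a count of few candidates is broken down. Candidates per tumour were compared by a two-sided exact permutation test over all splits into 5 and 5, recurrence by Fisher's exact test with Benjamini-Hochberg adjustment at 0.05, affinities on a log10 scale by a permutation test with 100000 resamples, and shares by Fisher's exact or exact binomial tests with 95% Clopper-Pearson intervals, which cover counting error only. The recurrence test was tested on simulated calls with the real number of calls per candidate, except in candidates set to 0 against 5 tumours. Of 40 such candidates among 142, 100% were recovered, with 0.05 false calls on average, and of 10 such candidates 0% were. At least 23 at the smallest possible p are needed for any to pass, so both recoveries were fixed by these numbers. Only 3 real candidates were called in exactly 5 tumours. Alternatives counted genes or lines in place of variants, left out each tumour in turn, used strong binders, recurrent candidates or the filtered table alone, and used medians. The planned comparisons of allele fraction and of base substitution class were not made, since the tables used here give neither. 1 planned item and the comparisons that rest on it are not reported here. Counts of private candidates, of cell-line candidates per tumour, the inferred C>A class and the H-2-Db share were added after the values were seen. Calculations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.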

Results

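Whole-exome sequencing was performed on mT3-2D, a mouse pancreatic cancer line of the KPC model on the C57BL/6 background, and on subcutaneous tumours grown from it. The 11 libraries comprised 1 of the cultured line, 5 of tumours from immunocompetent C57BL/6 (WT) mice and 5 of tumours from SCID mice, which lack mature T and B cells. The deposited tables list predicted neoantigens, that is, peptides of 9 residues that carry an amino-acid substitution and are predicted to bind the MHC class I molecules H-2-Kb or H-2-Db. Each peptide has a predicted affinity in nM (a lower value is stronger binding) and a number of occurrences per library. The full table held 159 lines, 149 mutant peptides and 128 gene names, which were merged to 142 candidates, each standing for 1 substitution. Libraries were sequenced to a mean depth of 200-fold per the labels. The depth at each substitution and its allele fraction were not used here, so a candidate not called in a library was not shown to be absent from it.

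Substitutions in Rrs1, Tm7sf3, Mansc4, Sirpb1b, Zfp534, the Ugt1a cluster and Mroh2a were called in all 11 libraries. These were 13 candidates, among them 5 of the 6 in Mroh2a and all 3 in the Ugt1a cluster of glucuronosyltransferases. Among candidates shared by the cell line and tumours, the peptide with the strongest predicted binding was TSWQQFARL of Rrs1, a ribosome biogenesis factor (chromosome 1, 9545408 to 9547455), with 7.61 nM against 168 nM for the reference peptide TRWQQFARL. QNYDYAVYL of Mrps35, a mitochondrial ribosomal protein (chromosome 6, 147042728 to 147070906), was predicted at 23.2 nM and was missing from WT-a alone. YLLHNAEFM of Ugt1a1 was predicted at 27.1 nM, IGIFFQMRV of Mroh2a at 48.3 nM and YAEKNRPPL of AC168977.1 at 53.0 nM. The last of these had a reference peptide at 6166 nM, a ratio of 116, and was missing from SCID-b alone. In all, 25 of the 43 candidates of the cell line were also called in a tumour, 24 of them in tumours of both hosts and 1, in Gadl1, in SCID tumours alone. The other 18 were called in the cell line alone. The strongest of these were RATRFFPKL of Rpgr at 36.3 nM, YSLRNLPSA of Ppp1r9a at 47.0 nM, SIRNFRMDL of Smarca1 at 49.9 nM, TSLRTYCDL of Rnf17 at 51.0 nM and TSTQNLSTL of the mucin Muc4 at 51.9 nM. Genes of families with close copies (Ugt1a, Sirpb1, Muc4, Duxf3 and the Zfp genes) share sequence, so the gene assigned to a call in them is uncertain.

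**Figure D1:**
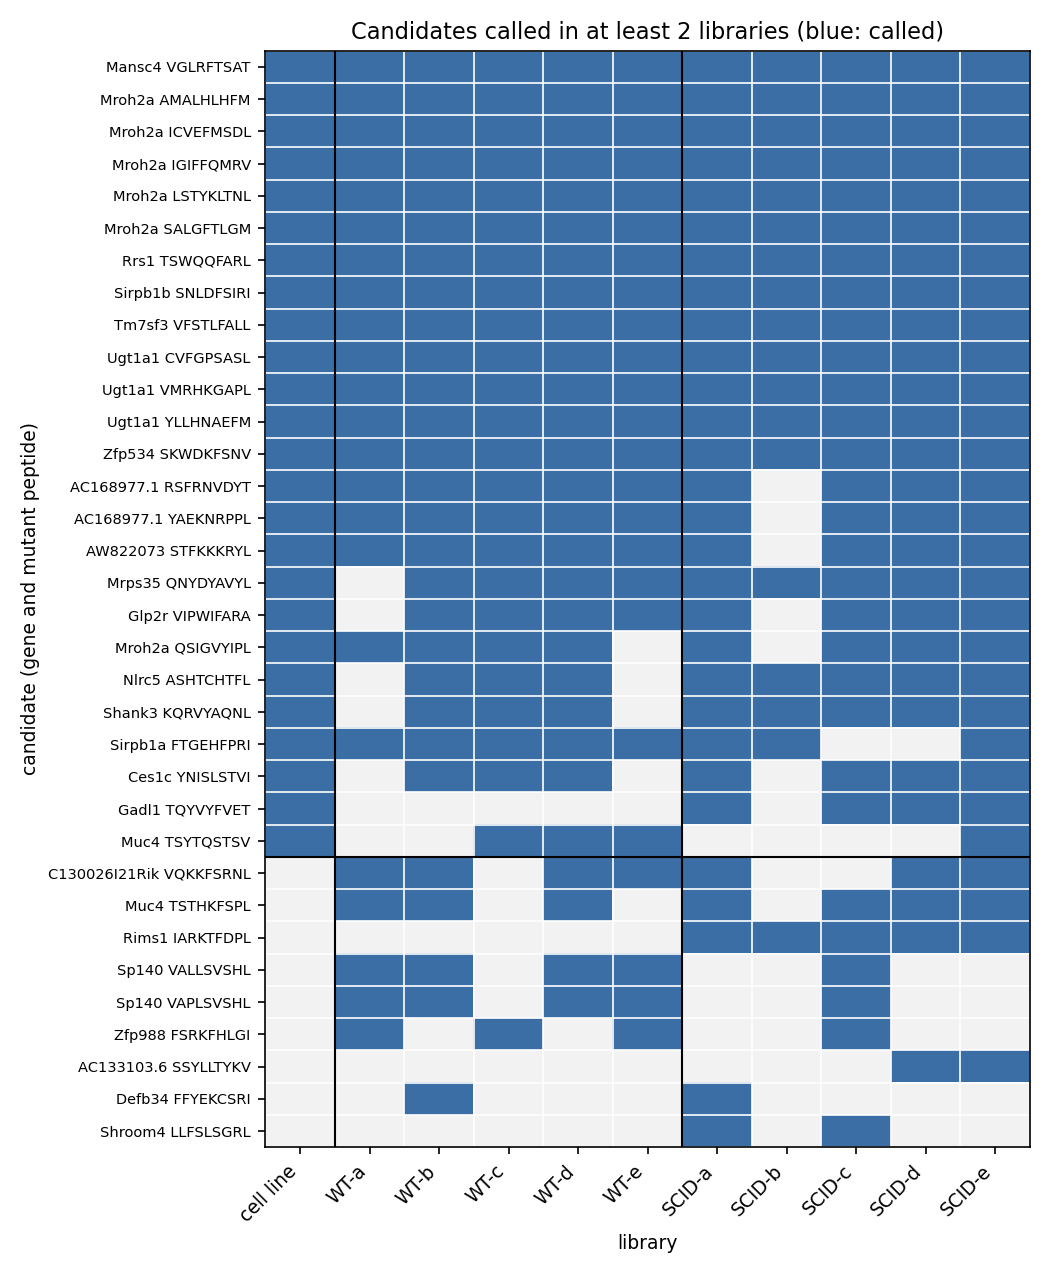
Presence of the 34 candidates called in at least 2 libraries, with the gene and mutant peptide on the vertical axis and the 11 libraries on the horizontal axis; blue cells are calls. The 25 rows above the line were called in the cell line, and Rims1, below it, was called in 5 of 5 SCID tumours and 0 of 5 WT tumours.

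The division of candidates by host asked which of them occurred in tumours with, and which in tumours without, adaptive immunity. Genes with the strongest WT-only peptides were Kif28, a kinesin (SAFLYVGFL, 13.5 nM), Adgre4, an adhesion receptor (IIWIFRSKL, 16.6 nM), Ces2h, a carboxylesterase (MAINNAFKI, 17.03 nM), Pask, a kinase (TAPVFFCDL, 20.9 nM), and Ran, a GTPase of nuclear transport (VTYKNVPNL, 22.4 nM). Those with the strongest SCID-only peptides were Nox4, an NADPH oxidase (KALSFFSNV, 7.15 nM), Piga, an enzyme of GPI anchor synthesis (ITVVVFSRL, 22.7 nM), Ccl28, a chemokine (VSHHVYGRL, 26.4 nM), Aebp2, a Polycomb cofactor (AALADMAYL, 27.6 nM), and Hsd17b13 (YCYSKFAAV, 56.6 nM). Each of these 10 was called in 1 tumour. A single base change can make the SCID-only changes named here, and that of Ran, only by C>A (or G>T on the other strand). The same held for 41 of the 61 WT-only and 23 of the 32 SCID-only candidates. Oxidation of DNA during library preparation, a known source of C>A calls, could not be told apart from mutation in the cells. Candidates shared by both hosts but not called in the cell line numbered 6, in Muc4 (TSTHKFSPL, 27.0 nM), Sp140 (2 candidates, the stronger VALLSVSHL at 97.7 nM), Zfp988 (142 nM), C130026I21Rik (151 nM) and the beta-defensin gene Defb34 (267 nM). WT-only candidates numbered 61 and SCID-only candidates 32, a WT-only share of 65.6% (95% exact interval 55.0% to 75.1%; two-sided exact binomial p = 0.00346). That test takes variants, not tumours, as its unit, and the number of candidates per tumour showed no difference between the hosts beyond its spread (exact permutation p = 0.246). Without WT-a, WT-b, WT-c or WT-e the share was 59.5%, 59.8%, 61.0% and 59.5% (exact binomial p = 0.115, 0.097, 0.0598 and 0.115), against an equal share although fewer WT than SCID tumours then remained. Among candidates in at least 2 tumours of a group, 0 were WT-only and 3 were SCID-only (Rims1, Shroom4 and AC133103.6; exact binomial p = 0.25).

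The number of candidates per tumour was 37.8 ± 1.48 (SD, n = 5) in WT mice and 32.2 ± 8.47 (SD, n = 5) in SCID mice, against 43 in the cell line. The difference of 5.6 did not exceed the spread between tumours (two-sided exact permutation test, p = 0.246) and was 2.3 without SCID-b (exact permutation p = 0.492). Single SCID tumours ranged from 19 to 40 candidates and WT tumours from 36 to 40. Candidates of the cell line, such as those in Rrs1 and Tm7sf3, numbered 21.8 ± 2.68 (SD, n = 5) in WT and 22.4 ± 3.13 (SD, n = 5) in SCID tumours (exact permutation p = 0.873). Private candidates, called in 1 library alone, such as those in Kif28 and Nox4, numbered 12.2 ± 1.79 (SD, n = 5) in WT and 5.8 ± 4.97 (SD, n = 5) in SCID tumours (exact permutation p = 0.0238). This comparison was chosen after the values were seen, as 1 of 7 measures per tumour (counts and the median affinity), and did not pass adjustment over them (Benjamini-Hochberg adjusted exact permutation p = 0.167). In the settings below that leave out tumours, private candidates were recounted over the remaining libraries. SCID-b held 1 and SCID-c 0 private candidates. Without both, the difference was 2.53 (exact permutation p = 0.179), without SCID-b alone it was 5.2 (exact permutation p = 0.0476), without SCID-c alone it was 4.7 (exact permutation p = 0.0794), and it missed the threshold at about its full size without WT-b (6.25, exact permutation p = 0.0635) and without SCID-d (6.7, exact permutation p = 0.0794). Counted by gene or in the authors' filtered table, the exact permutation p was 0.143.

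**Figure D2:**
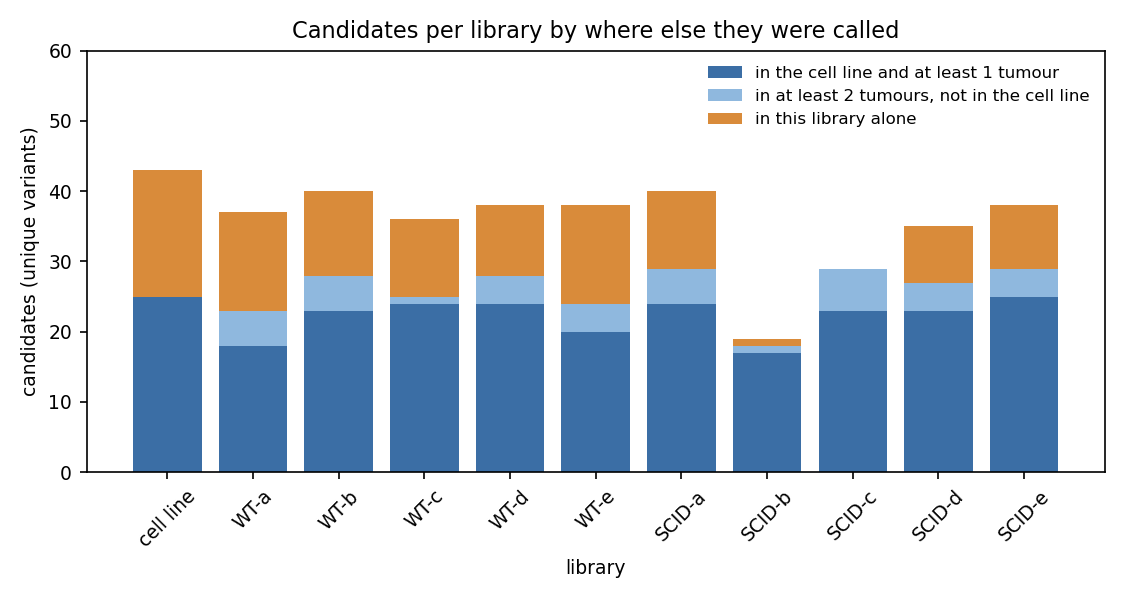
Number of candidates (unique variants, vertical axis) in each of the 11 libraries, divided into those also called in the cell line, those in at least 2 tumours but not in the cell line, and those in that library alone. SCID-b holds 19 and SCID-c 29 candidates, while the other tumours hold 35 to 40.

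Rims1 and Gadl1 were the candidates most unevenly distributed between tumours of the 2 hosts. IARKTFDPL of Rims1, a protein of the presynaptic active zone (chromosome 1, 22285972 to 22806158; 88.4 nM), was called in 5 of 5 SCID and 0 of 5 WT tumours and not in the cell line (two-sided Fisher's exact p = 0.00794, the smallest that 5 against 5 can give). Tumour tissue also holds host DNA, so the Rims1 calls can come from the SCID host and not the tumour cells, which was not tested. TQYVYFVET of Gadl1, a decarboxylase (chromosome 9, 115884671 to 116076176; 373 nM), was called in the cell line, in 4 of 5 SCID and in 0 of 5 WT tumours (Fisher's exact p = 0.0476). Both Sp140 candidates went the other way, with 4 of 5 WT and 1 of 5 SCID tumours in the library columns (Fisher's exact p = 0.206), although a reason in the authors' deposited table gives 3 of 5 WT mice for 1 of them. The 2 Sp140 candidates change the same serine and were called in the same libraries, so they are not independent of each other. Over all 142 candidates, 0 passed Fisher's exact test after Benjamini-Hochberg adjustment (smallest adjusted p = 1), and 2, Rims1 and Gadl1, had an unadjusted p under 0.05 (4 without WT-c and 4 without SCID-c, settings added after the values were seen). At least 23 candidates at the smallest possible p would have been needed for any to pass, and 3 were called in exactly 5 tumours, as that p requires, so this test could not have made a call. ASHTCHTFL of Nlrc5, the transactivator of MHC class I genes, and KQRVYAQNL of Shank3, a postsynaptic scaffold, were each called in the cell line, 5 of 5 SCID and 3 of 5 WT tumours (Fisher's exact p = 0.444). Both were missing from WT-a and WT-e, as was YNISLSTVI of the carboxylesterase Ces1c, which was also missing from SCID-b. FTGEHFPRI of Sirpb1a was called in 5 of 5 WT and 3 of 5 SCID tumours. Its occurrences were 5.2 ± 2.05 (SD, n = 5) in WT and 1.8 ± 2.05 (SD, n = 5) in SCID tumours (exact permutation p = 0.0794, adjusted p = 0.238 over the 3 peptides whose occurrences varied).

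Predicted binding strength was compared between 2 pairs of sets, and neither difference passed its test. WT-only candidates, led by Kif28, had a geometric mean of 131 nM and SCID-only candidates, led by Nox4, one of 133 nM, a difference of -0.01 in mean log10 affinity (SD 0.47, n = 61, and 0.44, n = 32; two-sided permutation test, p = 0.956). Candidates found in the cell line and both hosts, led by Rrs1, had a geometric mean of 142 nM against 132 nM for all others (n = 24 and 118; permutation p = 0.771). Variants of 1 tumour are not independent of each other, so these p-values describe variants and not mice. Strong predicted binders, under 50 nM, were 14 of the 61 WT-only candidates (22.95%, 95% exact interval 13.2% to 35.5%) and 4 of the 32 SCID-only candidates (12.5%, 3.51% to 29.0%). Mutant peptides ranged from 7.15 to 486 nM. The ratio of reference to mutant affinity had a median of 14.8 and ranged from 3.52 to 368, the value of Ces2h. It lay below 1 in 0 of 142 candidates, which the authors' selection can fix, so the planned test of mutant against reference peptides was not made.

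**Figure D3:**
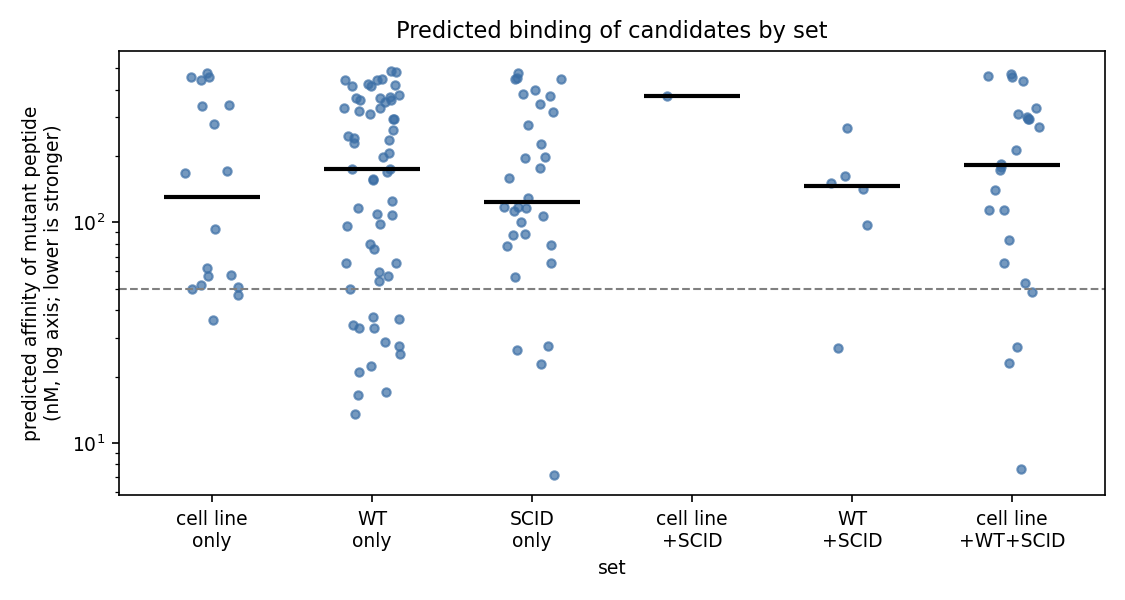
Predicted affinity of the mutant peptide (nM, log axis, lower is stronger) for each candidate, by set; points are candidates, bars are medians and the dashed line marks 50 nM. The medians are 175 nM for WT-only and 123 nM for SCID-only candidates, and single values span 7.15 to 486 nM.

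H-2-Kb was the predicted MHC molecule of 113 of the 142 candidates (79.6%, 95% exact interval 72.0% to 85.9%) and H-2-Db of 29. Over all sets, the planned test of allele use did not pass the threshold (two-sided Fisher's exact test by Monte Carlo, p = 0.329). H-2-Db made up 26.2% of WT-only and 9.38% of SCID-only candidates, a contrast added after the values were seen (Fisher's exact p = 0.0632, and 0.0369 over all lines). The test over all lines counts peptides of the same substitution separately. Neither test takes tumours as its unit. Of the H-2-Kb candidates, 60 gained a tyrosine or phenylalanine at position 3, 5 or 6 of the peptide, as in Ccl28, Mrps35 and Rims1, and 22 gained leucine, valine, isoleucine or methionine at position 9, as in Kif28, Nox4 and Ran. Of the H-2-Db candidates, 8 gained an asparagine at position 5, as in Ces2h, Zfp763 and Muc4.

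Of the gene lists fixed before the data were examined, variable multigene families held the most candidates, 20 in 14 genes, of which 13 were WT-only and 2 SCID-only. They included Muc4 in 4 different sets, Muc16 (TTTAFYPSI, 108 nM), Zfp661 (KAFFYRSSL, 28.6 nM) and Zfp763 (KAFINSSHL, 109 nM). Cytoskeleton and motor genes held 6 candidates, 5 of them WT-only, in the kinesin Kif28 and the dynein heavy chains Dnah3 (KWIIFYGPV, 54.1 nM) and Dnah14 (VLYDIMSQL, SCID-only, 158 nM). Matrix and adhesion genes held 3, in Cdhr4 (34.3 nM, WT-only), the collagen Col4a5 (87.7 nM, SCID-only) and the protocadherin Pcdh9 (157 nM, WT-only). Antigen presentation held 1, in Nlrc5 (295 nM). The lists of pancreatic cancer drivers, interferon signalling, DNA repair, chromatin, very long genes and immune cell markers held 0 candidates. Trp53 and Prkdc were not candidates. A candidate is a substitution in a peptide predicted to bind, so a gene without one can still be mutated. No enrichment was tested, since the genes that could have given a candidate are not known from the tables.

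The authors' top candidates were 19 peptides in 20 lines, 12 lines at high and 8 at medium priority. They were drawn mainly from the set found in the cell line and both hosts, with 15 of 19 peptides (78.9%, 95% exact interval 54.4% to 93.9%). High-priority genes included Rrs1, AC168977.1, Tm7sf3 (VFSTLFALL, 184 nM), Zfp534 (SKWDKFSNV, 455 nM) and all of the authors' WT and SCID picks. The 5 WT picks were AC168977.1, Duxf3 (STFKKKRYL, 140 nM, with the same peptide listed for AW822073), Glp2r (VIPWIFARA, 214 nM), Muc4 (TSYTQSTSV, 308 nM) and Sirpb1a (471 nM). The 5 SCID picks were Ces1c (437 nM), Gadl1, Nlrc5, Shank3 (296 nM) and Tm7sf3. All 5 WT picks and 4 of the 5 SCID picks, all but Gadl1, were called in the cell line and in tumours of both hosts. Their names therefore do not mark candidates of 1 host. Medium priority held C130026I21Rik, Mansc4 (VGLRFTSAT, 328 nM), Mroh2a (LSTYKLTNL, 173 nM), Rims1, Sirpb1b (SNLDFSIRI, 65.7 nM), Sp140, Ugt1a1 (VMRHKGAPL, 113 nM) and AW822073. These were chosen by the authors on the same libraries and are not independent evidence. Of the 139 excluded lines, the authors' deposited table gives 64 as seen in 1 mouse and not in the cell line, 35 as seen in 1 or 2 mice and not in the cell line, and 18 as seen in the cell line alone. For the 64 and the 35 lines the authors added that the change was possibly germline or a cancer mutation that did not reproduce. They marked the excluded Ugt1a lines as polymorphic. Some other lines were excluded for a less favourable score or ratio than another candidate of the gene, such as 4 lines of Mroh2a. The reasons for the 64, 35 and 18 lines rest on the libraries in which a candidate was called. The planned test of set composition between kept and excluded candidates would therefore largely restate the selection and is not given. A note of Sanger sequencing stood at 14 lines of the authors' deposited table, and 7 of these, in AW822073, Glp2r, Mansc4, Mrps35, Nlrc5, Shank3 and Tm7sf3, carried a further positive remark. The authors' filtered table kept 119 of the 142 candidates (83.8%) and left out all 14 Zfp, 6 Mroh2a and 3 Ugt1a candidates. Of the Zfp candidates, 11 were WT-only and 1 was SCID-only. In the filtered table the WT-only share was 61.7% (50 against 31; exact binomial p = 0.0448).

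Chromosomes 16 and 11 were compared between sets as planned. Chromosome 16, which holds Prkdc (15637444 to 15842239), the gene mutated in SCID mice, held 1 of 30 SCID-only and 2 of 60 WT-only candidates with a position (two-sided Fisher's exact p = 1). Chromosome 11, which holds Trp53 (69580348 to 69591873), held 1 of 23 candidates shared with the cell line, Glp2r (67664156 to 67771184), and 4 of 112 others (Fisher's exact p = 1). Neither test passed the threshold. The 9 candidates of Ugt1a1 and Mroh2a lay within 50.3 kb of chromosome 1 (88211959 to 88262289).

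The amino-acid changes of private candidates differed from those of recurrent ones, a comparison chosen after the values were seen in place of the planned one on base changes, which the tables do not give. Changes that a single base change can make only by C>A (or G>T on the other strand), such as aspartate to tyrosine in Col4a5, Dnah3 and Zfp661, were 75 of 108 private candidates (69.4%, 95% exact interval 59.8% to 77.9%). They were 5 of 34 candidates called in at least 2 libraries (14.7%, 4.95% to 31.1%; two-sided Fisher's exact p = 1.83e-08). Private candidates of WT tumours had 41 of 61 such changes and those of SCID tumours 22 of 29 (Fisher's exact p = 0.468). Both tests take variants, not tumours, as their unit, and variants of 1 tumour or gene are not independent. Among the recurrent candidates, 9 lay within 50.3 kb in Ugt1a1 and Mroh2a. The p-values and intervals therefore describe these variants and can overstate the evidence.

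**Figure D4:**
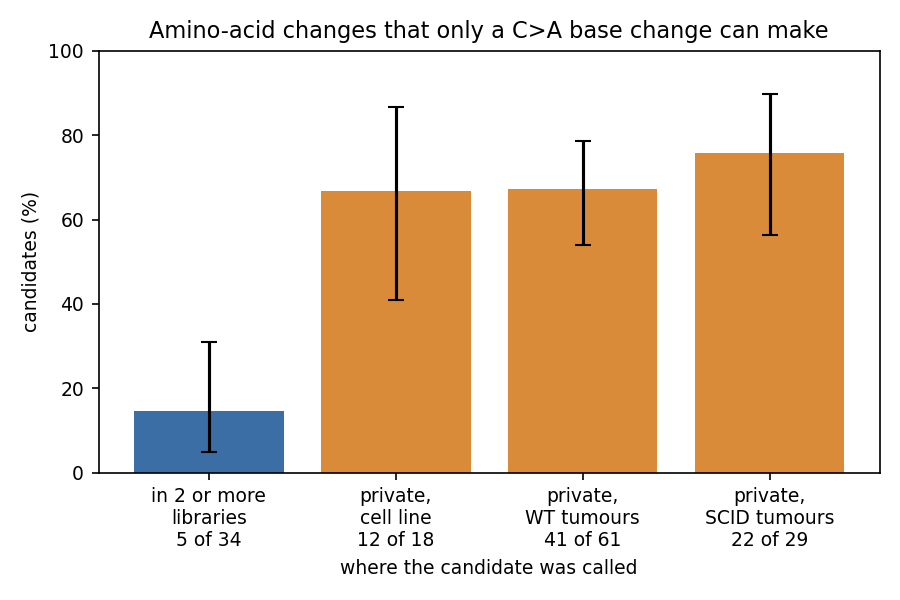
Percent of candidates whose amino-acid change only a C>A base change can make (vertical axis), for candidates in 2 or more libraries and for private candidates of the cell line, WT and SCID tumours; error bars are 95% exact binomial intervals. The share is 14.7% in recurrent and 66.7% to 75.9% in private candidates.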

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

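All tests in this part were chosen after the values were seen. Among 12 groups of 5 values tested, 2 held a tumour far from the others of its host, where chance gives about 1 in 20. The groups hold measures of the same tumours and are not independent of each other. SCID-b carried 17 of the 25 cell-line candidates shared with tumours, lacking among others both AC168977.1 candidates, Duxf3, Glp2r, Ces1c and Gadl1, while the other SCID tumours carried 23 to 25. WT-c carried 1 candidate that was in at least 2 tumours and not in the cell line, Zfp988, while the other WT tumours, which held Sp140 and C130026I21Rik, carried 4 or 5. The 2 Sp140 candidates in these counts change the same serine and are not independent. The rule was Dixon's ratio, the gap to the nearest value over the range, which was 0.75 for WT-c against a critical value of 0.71. With the Sp140 candidates counted as 1, WT-c would lie under that critical value and would not be flagged.

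SCID-b and SCID-c held 1 and 0 private candidates, against 8 to 14 in the other 8 tumours. Fewer reads or fewer tumour cells in these samples could lower such numbers. SCID-b had 17 cell-line candidates, fewest of the tumours, but WT-a had 18 and yet 14 private candidates, and the gap of SCID-b to WT-a is under the SD of 2.24 over the 9 tumours other than SCID-b, so this explanation stays open. SCID-c had 23, near the median of 23.5 of the 8 other tumours, and the explanation cannot be told apart from others there without depth or allele fractions. The immune status of the host also stays open. Among the remaining tumours, 3 SCID and 5 WT, the exact permutation p was 0.107 with private candidates as counted over all libraries. With private candidates recounted without SCID-b and SCID-c, the exact permutation p was 0.179. Both comparisons leave out libraries for their values.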

How the results depend on the processing

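Of the settings given here, the filtered table, unique peptides, candidates in at least 2 libraries, the joint omission of SCID-b and SCID-c, and leaving out tumours for any result other than candidates per tumour and adjusted recurrence calls were chosen after the values were seen, as was every setting for private candidates, cell-line candidates per tumour, the C>A class and the H-2-Db share. No paired analysis was possible because the library columns carry no replicate numbers. Allele fractions and base classes were not run. Of 157 alternatives over 16 results, 16 could not have changed anything and say nothing about stability: the excluded lines are part of the full table, every peptide lies under 500 nM, and no recurrence call was possible with 1 tumour left out (10 settings). Another 11 concern chromosome 16, whose difference of 0 has no direction to keep (-3.33 to 1.72 percentage points, none past the threshold). Of the other 130, 108 kept direction and side of the threshold or, for values without a test, stayed near the main value. The difference in candidates per tumour passed the threshold under none of the settings run (2.3 more in WT without SCID-b, and up to 7.55 more when another tumour was left out); among candidates in at least 2 libraries, which leaves out all private ones, the difference turned to -0.8 (exact permutation p = 0.865). The WT-only share was 59.5% to 74.7% when 1 tumour was left out and lost its call without WT-a, WT-b, WT-c or WT-e, each of which removes WT-only candidates by construction; it was 0% among candidates in at least 2 tumours of a group, where 3 remained. Private candidates per tumour differed by 4.7 to 7.65 when 1 tumour was left out, by 4.6 counted by gene, by 4.4 in the filtered table and by 2.53 without SCID-b and SCID-c, and the call was lost in the last 3 and without WT-b (6.25, exact permutation p = 0.0635), SCID-c (4.7, p = 0.0794) or SCID-d (6.7, p = 0.0794); the cause was not tested. Cell-line candidates per tumour differed by -1.95 to 0.35 when 1 tumour was left out, never past the threshold. The binding difference between WT-only and SCID-only candidates, near 0, turned to 0.15 in medians (permutation p = 0.501) and lay between -0.0627 and 0.0329 when 1 tumour was left out; the cause was not tested. The chromosome 11 difference turned to -0.36 percentage points counted by gene. The C>A share differed between private and recurrent candidates by 44.9 to 60.04 percentage points over 13 settings, all past the threshold in tests that do not take tumours as their unit. Depth at each site is unknown, so how far missed calls limit these numbers was not measured.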

Other observations

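Apart from the planned count of recurrence calls, the tests in this part were chosen after the values were seen. X-linked genes gave 5 of 30 SCID-only candidates with a position, in Col4a5, Ocrl, Piga, Shroom4 and Spry3, and 1 of 60 WT-only candidates, in Sox3 (unadjusted Fisher's exact p = 0.0147, singled out from a look at every chromosome). Ocrl and Piga were called in SCID-a alone, Shroom4 in SCID-a and SCID-c, and Col4a5 and Spry3 in SCID-e alone. That test takes variants, not tumours, as its unit, so it does not describe SCID tumours as a group. Tyrosine was the residue gained most often, in 48 of 142 candidates, followed by phenylalanine in 23 and leucine in 18. Sp140 and C130026I21Rik, neighbours at 0.305 Mb on chromosome 1, were both called in WT-a, WT-b, WT-d and WT-e and not in WT-c. The SCID tumours did not show this pairing. Among them, Sp140 was called in SCID-c alone and C130026I21Rik in SCID-a, SCID-d and SCID-e, so none held both.

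Rims1 and Gadl1 were the 2 candidates with an unadjusted Fisher's exact p under 0.05 between WT and SCID tumours. For the planned count past the adjusted threshold, which was 0, all 100 of 100 drawn splits of the 10 tumours gave as many, with 0 in the highest other split. This outcome was fixed, since no placement of these candidates among the 10 tumours could bring an adjusted p below 0.376, and it says nothing about chance. For the unadjusted count of 2, 2 of 100 drawn splits gave as many, the real one included, and the highest other split gave 2; this count was turned to only after the planned one was 0.

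Private candidates, such as those in Ccl28, Col4a5 and Pcdh9, mostly carried changes that only C>A can make. Among candidates that gained a tyrosine, the source was aspartate or serine in 41 of 42 private and 2 of 6 recurrent candidates (Fisher's exact p = 0.000371, with variants as its unit). Both changes can be made only by C>A, so the contrast remained among candidates with the same gained residue. Whether selection for predicted MHC binding contributed cannot be decided this way. It can also act on the lost residue, through the reference peptide's score, and the ratio of reference to mutant affinity was at least 3.52. The pattern was not confined to tumours. The cell line's own private candidates, such as Rnf17, had a share of 66.7% (95% exact interval 41.0% to 86.7%), above the 14.7% of recurrent candidates. This argues against growth in mice as the only source of the pattern. Whether the private changes of the tumours arose in the mice is not decided by it, since it concerns other candidates. Oxidation of DNA during library preparation, a known source of C>A calls, could account for the pattern and cannot be told apart from C>A mutation in the cells: the lowest share in a library with at least 8 private candidates was 50%, and no allele fractions or read orientations were used here. No biological explanation beyond growth in mice was tested.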
